A study of Mus musculus with 34 samples.

How the data were processed

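Single germinal vesicle oocytes of mouse were profiled by RNA-seq, 17 from females with floxed Ube2i and no cre (control) and 17 with floxed Ube2i and Zp3-cre (cKO). Per the labels' protocols, cDNA was made from each oocyte with the SMART-seq v4 kit, which does not keep strand, and libraries were made with Nextera XT. STAR, featureCounts and DESeq2 and the build GRCm38 are named in the submitters' processing notes, and their versions are not given in the sources used here. The kit counts reads without molecular identifiers, so intervals from reads cover counting error only.

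The deposited table holds 26201 genes in 34 columns, and its values are a signal per gene that the authors normalised between oocytes. Per the submitters' processing notes DESeq2 was used, and the values of the deposited signal were whole reads divided by 1 size factor per column: reads were recovered as whole numbers within 0.01 for 100% of values, and size factors recomputed from those reads by DESeq2's rule matched. The lowest total of a gene over all oocytes was 11 reads. Gene symbols, coordinates and overlaps were taken from GENCODE release M21 for GRCm38, which matched 26144 of the identifiers and left 57 without a symbol. The column whose name matched no title was used as a cKO oocyte of the unit number in its name, 6300.

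The number in the code of an oocyte was taken as the replicate unit, giving 5 control units (6292, 6295, 6296, 6297 and 6323) and 5 cKO units (6299, 6300, 6301, 6302 and 6322) of 2 to 5 oocytes. Genes with a value of at least 10 in at least 8 oocytes were tested, 15326 in all. The mean of log2(value + 1) over the oocytes of a unit was compared between groups with limma 3.58.1 (trend and robust options, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. For genes with 1 to 3 reads in control, the ratio of reads per size factor is given with its exact 95% interval in place of a fitted fold. Tested on simulated data for this comparison over 15011 genes, the fit recovered 63.3% of genes changed 2-fold and 96.9% of those changed 4-fold, and 6.63% of its calls were unchanged genes. The simulation changed 98 and 96 genes by these folds, in either direction and with known size factors. Its shares need not hold in the data, where 7059 genes were called.

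Gene lists (30) were fixed before the data were examined. For each list, limma's camera with a preset correlation of 0.01 was run, with an estimated correlation and fry as alternatives. Of the list entries, 13 were matched through a synonym and 6 had no gene. The median of each list was also set against 10000 random lists matched on mean level, a description added after the data were seen. Named genes followed a rule fixed before the data were examined. The rule takes Ube2i, then the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a mean of at least 50 in the higher group, separate unit means and an assigned symbol. It then takes up to 4 members of each list with the smallest p and a fixed set of oocyte, Zscan4 and chromatin genes. Some members of the fixed lists were named after the results were seen, as were the genes in the other observations. These list members are Zfp54, Usp26, Tmem92, Arg2, Nr5a2, Amh, Foxl2, Amhr2, Inha, Cd74, Lyz2, Col1a1, Col3a1 and Tyrobp.

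Detected genes were counted at 5 reads or more after the reads of every oocyte were thinned to 4902488, the lowest total. The distance of an oocyte to its group was 1 minus the Spearman correlation with the mean profile of the other units. Both were compared with exact two-sided permutation tests of the unit means (252 relabellings, smallest p 0.00794) in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. In the counts of all pairs of oocytes within a group the lowest chi-square per gene was 7.61, so all 34 libraries were counted as separate.

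Alternatives changed the pseudocount, the filter, the scaling (a common total per oocyte, quantile normalization), the replicate unit, the way oocytes were combined, and the test (edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads). Each unit was left out in turn, and units 6322 and 6323, which carry the highest library tags, were left out together. Tags of the other units run in 1 block for control and the next for cKO, so an effect of tag order could not be separated from the group among them. Reads ranged from 4902488 to 18571036 per oocyte, so a gene without a read in any oocyte of a group was not detectable at this depth, and 3 reads over a group set the floor.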

Results

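Poly(A) transcript levels were measured in single mouse oocytes at the germinal vesicle stage, in which the oocyte is arrested in meiotic prophase and transcription is being shut down. The control group held 17 oocytes with both Ube2i alleles floxed and no cre, and the conditional knockout (cKO) group held 17 oocytes with the same alleles and Zp3-cre, which is active in growing oocytes. Ube2i encodes the E2 enzyme that conjugates SUMO, a small protein modifier, to its targets. The oocytes carry codes whose number is shared by several oocytes, and the numbers formed 5 units in each group, with 2 to 5 oocytes each. The labels do not say that a number is an animal, so p-values measure the spread between these units, which may be technical. Reads counted in genes ranged from 6944041 to 18571036 per control oocyte (median 10807311) and from 4902488 to 11708142 per cKO oocyte (median 6640004). Levels are given below as normalised counts (reads divided by the size factor of the oocyte), as the mean ± SD of 5 unit means per group (n = 5), and log2 fold changes of cKO over control carry their SE on the log2(value + 1) scale. No spike-in values were used, so all levels are relative to the other genes of an oocyte.

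The targeted gene itself was compared first. Ube2i (chromosome 17, 25261916 to 25274622, minus strand) was counted at 2745 ± 180.2 in control and 1355 ± 65.0 in cKO (log2 fold change -1.02 ± 0.10, limma adjusted p = 2.48e-06). In an exact two-sided permutation test of the unit means the difference had p = 0.00794, the smallest that all relabellings of 5 against 5 can give. Single oocytes ranged from 2383 to 3235 in control and from 1043 to 1451 in cKO, so the groups did not overlap in any of the 34 oocytes. The count covers the whole gene, and the floxed exons are not given in the sources used here, so the cKO value can include reads from outside the deleted part.

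**Figure D1:**
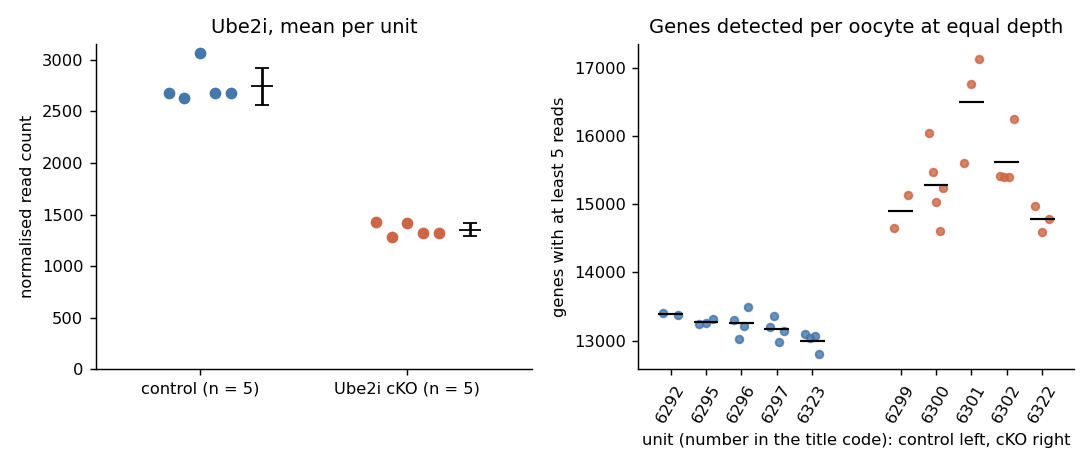
Left, Ube2i normalised counts; right, number of genes with at least 5 reads after every oocyte was thinned to 4902488 reads. On the left, points are unit means and bars are the mean ± SD of 5 units for control and cKO. On the right, points are oocytes and horizontal lines are unit means. Ube2i lay lower in every cKO unit than in any control unit. The number of detected genes lay higher in every cKO oocyte than in any control oocyte.

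To ask how the transcriptome of cKO oocytes differs, 15326 genes were tested. Of these, 7059 differed between the groups, 4177 higher and 2882 lower in cKO (limma on unit means, Benjamini-Hochberg adjusted p below 0.05). On the log2(value + 1) scale 563 genes were at least 10-fold higher and 40 at least 10-fold lower. All 5 cKO units lay above all 5 control units for 3051 genes and below for 1964, together 32.7% of the tested genes, where chance gives 0.794%. The direction depended on the level of the gene. In the lowest of 5 equal bins (mean 4.01 to 21.04) 41.3% of the genes were higher and 9.92% lower, and in the highest bin (mean 608 to 60348) 9.69% were higher and 34.6% lower. The balance also depended on the scaling. The share of higher calls was 59.2% as deposited, 78.0% with a common total per oocyte (5530 higher, 1559 lower) and 43.0% with quantile normalization (2968 higher, 3927 lower). The median log2 fold change of all genes was 0.05, 0.30 and -0.11 under these scalings.

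**Figure D2:**
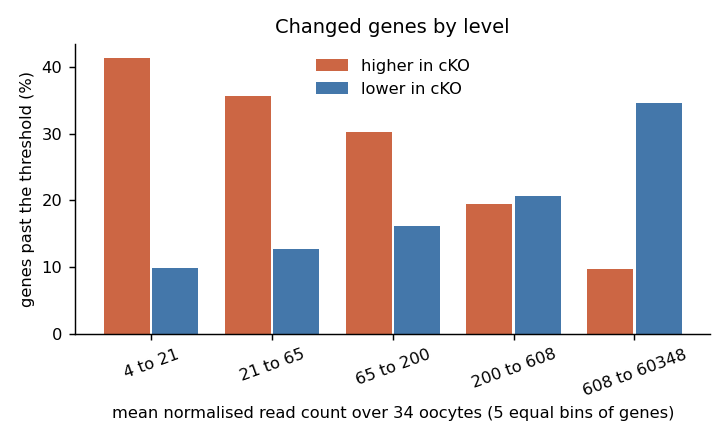
Share of tested genes higher and lower in cKO (percent, y axis) in 5 bins of equal size ordered by mean normalised count (x axis). The share of higher genes was 41.3% in the lowest bin and 9.69% in the highest, and the share of lower genes was 9.92% and 34.6%.

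The genes with the largest rise were close to silent in control oocytes. Mt1, which encodes a metal-binding metallothionein (chromosome 8, 94179082 to 94180327, plus strand), rose from 20.1 ± 5.69 to 8377 ± 1640.1 (log2 fold change 8.89 ± 0.22, adjusted p = 4.14e-12). Krt79, an epithelial keratin (chromosome 15, 101929332 to 101940324, minus strand), rose from 6.64 ± 3.00 to 2001 ± 151 (log2 fold change 8.48 ± 0.25). Bglap3, of the osteocalcin family, rose from 13.8 ± 4.31 to 1633 ± 210.2 (log2 fold change 7.04 ± 0.26). Clrn3 rose from 0.379 ± 0.582 to 855 ± 97.2 and Tmem40 from 0.490 ± 0.543 to 531 ± 146. Ifi27l2a rose from 1.98 ± 2.11 to 821 ± 165 and Samd11 from 0.527 ± 0.583 to 214 ± 46.9. The deubiquitinase genes Usp17lc and Usp17lb rose from 2.48 ± 2.81 to 1324 ± 808 and from 8.92 ± 5.99 to 3848 ± 4592. They belong to a family of near-identical copies, so their counts are uncertain. Igha and Ighe encode the constant regions of the antibody heavy chains alpha and epsilon. Igha had 1 read over the control oocytes and 14291 over the cKO oocytes, a ratio of 17840.1 with a 95% counting interval of 3201 to 704697. Ighe had 1 read over the control oocytes and 10571 over the cKO oocytes, a ratio of 13196 with a 95% counting interval of 2368 to 521274. Itpkb, an inositol trisphosphate kinase, had 1 read over the control oocytes and 2962 over the cKO oocytes, a ratio of 3698 with a 95% counting interval of 663 to 146096. These intervals cover counting error only. The cKO mean of Usp17lb was 1874 without cKO unit 6301. The control means were 0.1435 for Clrn3 and 1.27 for Usp17lc without control unit 6295, 1.07 for Ifi27l2a without unit 6292 and 0.3215 for Tmem40 without unit 6297. Tmem40, Usp17lc, Samd11 and Itpkb overlap other annotated genes, and the library kit does not keep strand.

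The genes with the largest fall were of moderate level in control oocytes. Tuba3b, an alpha-tubulin of a multi-copy family (chromosome 6, 145615757 to 145621479, plus strand), fell from 1108 ± 438 to 60.2 ± 94.8 (log2 fold change -5.13 ± 0.60, adjusted p = 4.03e-05). Akap6, which anchors protein kinase A, fell from 55.7 ± 13.0 to 1.23 ± 1.51 (log2 fold change -4.94 ± 0.40). Ece1, the endothelin-converting enzyme, fell from 87.2 ± 22.1 to 4.63 ± 1.93 (log2 fold change -4.29 ± 0.31). Cth, cystathionine gamma-lyase, fell from 223 ± 63.6 to 12.9 ± 3.87. Hormad2, a protein of the meiotic chromosome axis, fell from 69.5 ± 13.6 to 3.81 ± 0.835, and Ppp3ca, a catalytic subunit of calcineurin, from 86.8 ± 17.6 to 7.37 ± 3.86. Msi2, Pgap1, Tctex1d1, Bpifc and Tmc7 also fell, with log2 fold changes between -4.24 and -3.87. Igf1os, annotated antisense to Igf1, fell from 194 ± 43.5 to 19.8 ± 24.7, and without strand its reads cannot be told from those of Igf1. The cKO means of Tuba3b and Igf1os were 17.9 and 8.91 without cKO unit 6300, and that of Akap6 was 0.715 without unit 6302. Akap6, Ece1, Msi2, Pgap1, Cth, Tctex1d1 and Ppp3ca overlap other annotated genes.

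**Figure D3:**
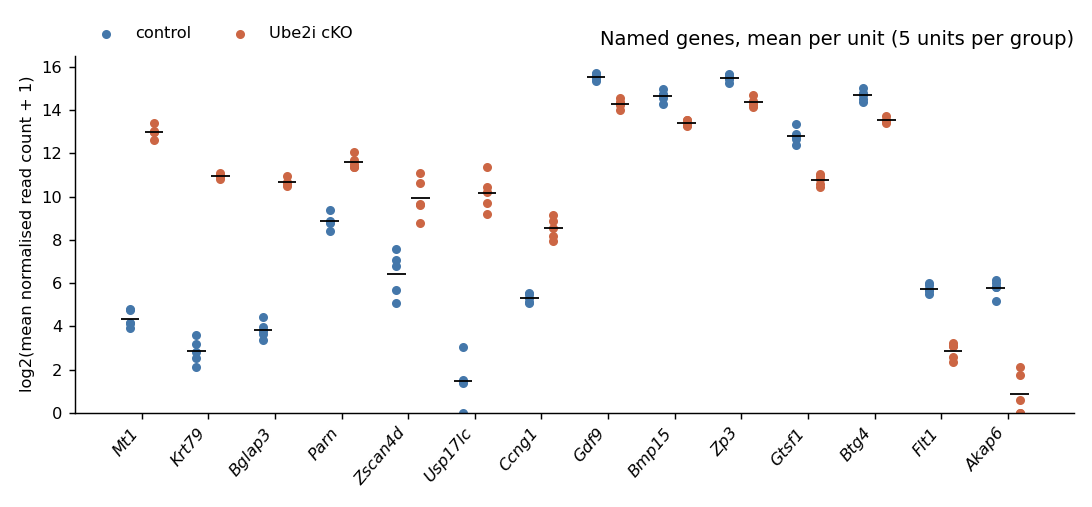
Normalised counts of 14 named genes, as log2(unit mean + 1) on the y axis; each point is a unit, control beside cKO, and each bar is the mean of 5 units. Mt1, Krt79, Bglap3, Parn, Zscan4d, Usp17lc and Ccng1 lay higher and Gdf9, Bmp15, Zp3, Gtsf1, Btg4, Flt1 and Akap6 lower in all cKO units than in all control units.

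Among 30 gene lists fixed beforehand, the two-cell and genome activation list, of genes normally switched on in the early embryo, moved most. 28 of 35 measured members were higher and 1 lower in cKO (28 and 1 adjusted over the list alone), and 6 did not pass. The median log2 fold change was 3.88 (camera adjusted p = 6.80e-07, and adjusted p = 0.459 with an estimated correlation). It was 4.72 with the 8 members of at most 3 control reads at the lower bound of their ratio. That bound covers counting error of reads pooled over oocytes and leaves out the spread between units. It is not on the log2(value + 1) scale, so 4.72 is no conservative form of 3.88. Zscan4d rose from 104 ± 64.4 to 1155 ± 704 (log2 fold change 3.5 ± 0.44) and Zscan4f from 3.18 ± 4.22 to 265 ± 219.8. Zscan4c rose from 42.8 ± 34.2 to 572 ± 626 with overlapping units. Zscan4b rose from 0.215 ± 0.14 to 245 ± 423. Zscan4a had 1 read over the control oocytes and 9904 over the cKO oocytes, a ratio of 12364 with a 95% counting interval of 2219 to 488387. Zscan4e had 2 reads over the control oocytes and 2739 over the cKO oocytes, a ratio of 1709.6 with a 95% counting interval of 473 to 14124. The cKO units of both were uneven, with means of 814 ± 1484 for Zscan4a and 186 ± 249 for Zscan4e. Without cKO unit 6301 these means were 156 and 88.6 and the ratios 3632 and 1098.8. The calls of Zscan4a and Zscan4b were lost under quantile normalization (adjusted p = 0.0641 and 0.0746) and with a pseudocount of 10 (adjusted p = 0.0923 and 0.0929). Pramef25, Usp17le and Gm20767 rose to 420.4 ± 355 from 5.77 ± 1.88, 616 ± 542 from 3.75 ± 1.96 and 677 ± 358 from 8.02 ± 3.51. Without cKO unit 6301 the cKO means of Zscan4b, Zscan4c, Pramef25 and Usp17le were 58.5, 306, 269.7 and 389.9. Without control unit 6295 the control means of Zscan4c and Zscan4f were 27.6 and 1.36. Most of these genes belong to families of near-identical copies, so their counts are uncertain. Among the 6 measured members of no multi-copy family, 1 rose (Zfp54), 1 fell (Usp26) and the median log2 fold change was 0.23. Tmem92, at 19.3 ± 3.32 in control and an uneven 519 ± 857 in cKO, did not pass (limma adjusted p = 0.0887).

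**Figure D4:**
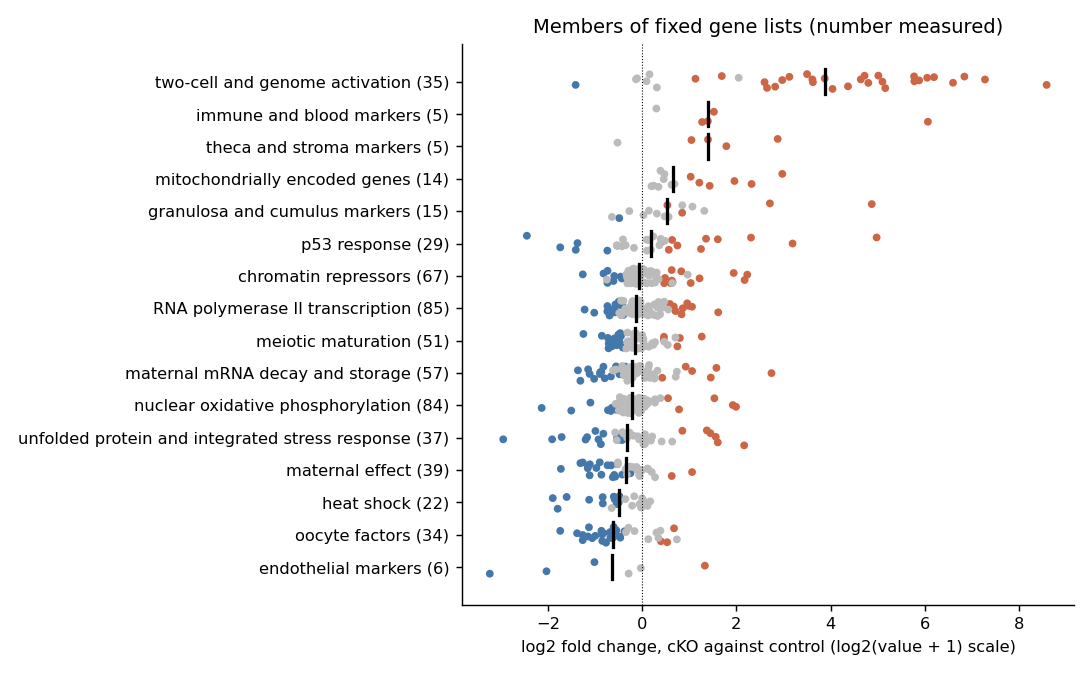
Log2 fold changes of cKO over control (x axis) of the members of 16 gene lists; points are genes, coloured where the adjusted p is below 0.05, and bars are list medians. The median was 3.88 for the two-cell list, -0.61 for oocyte factors and -0.35 for maternal effect genes.

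The abundant products of the growing oocyte were lower. In the list of oocyte factors 3 of 34 measured members were higher and 23 lower in cKO (3 and 23 adjusted over the list alone), and 8 did not pass. The median log2 fold change was -0.61 (camera adjusted p = 3.21e-06, and adjusted p = 0.110 with an estimated correlation). The secreted growth factors Gdf9 and Bmp15 both fell. Gdf9 went from 48039 ± 5529 to 20186 ± 2719 (log2 fold change -1.26 ± 0.12) and Bmp15 from 25949 ± 4306 to 10742 ± 954 (log2 fold change -1.26 ± 0.12). The zona pellucida genes Zp1, Zp2 and Zp3, which encode the coat of the egg, also fell. Zp1 went from 12534 ± 1966 to 6331 ± 889, Zp2 from 38353 ± 2844 to 19926 ± 6521 and Zp3 from 46249 ± 5072 to 21242 ± 3411. Oosp3 fell from 8919 ± 2649 to 2569.7 ± 260.0 and the oocyte linker histone H1foo from 54829 ± 4075 to 30520.3 ± 1793. The transcription factor Nobox rose from 6309 ± 1458 to 9007 ± 1280.1 (adjusted p = 0.0130). Figla was counted at 465 ± 142 in control and 559 ± 107 in cKO (adjusted p = 0.229). It passed under a common total per oocyte (log2 fold change 0.56, adjusted p = 0.0256), with a block of the oocyte numbers (0.0364) and without control unit 6296 (0.0369). Under a common total 6 members were higher and 17 lower. Under quantile normalization 2 were higher and 10 lower, the list median was -0.10, the list no longer passed (adjusted p = 0.750), and Zp2 and H1foo no longer passed (adjusted p = 0.187 and 0.835). The list median lay at percentile 0.440 of random lists matched on mean level, whose median was -0.38.

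In the maternal effect list, of stored products needed after fertilisation, 2 of 39 measured members were higher and 19 lower in cKO (2 and 21 adjusted over the list alone), and 18 did not pass. Its median was -0.35 (camera adjusted p = 2.96e-05, and adjusted p = 0.205 with an estimated correlation). Btg4, an adaptor of mRNA deadenylation, fell from 26620.4 ± 4903 to 11998 ± 1031 (log2 fold change -1.15 ± 0.12), and Zar1, which binds stored mRNA, from 13057 ± 3516 to 5139.7 ± 819. The argonaute gene Ago2 fell from 760.2 ± 92.0 to 239.8 ± 67.7 and the histone chaperone Npm2 from 12969 ± 2625 to 6996 ± 580.2. Dppa3 and Nlrp5 fell from 33114 ± 9958 to 22316 ± 4607 and from 20499 ± 2450.3 to 14177 ± 3216. These calls were lost under both other scalings, with log2 fold changes of 0.20 and 0.10 under quantile normalization. That of Dppa3 was also lost without cKO unit 6299 or 6322 (adjusted p = 0.0517 and 0.0539) and with the oocyte of the unmatched column as its own unit (adjusted p = 0.0950). Members lower numbered 12 under a common total and 10 under quantile normalization, with 2 higher in each, and the list no longer passed under quantile normalization (adjusted p = 0.750). Its median lay within the range of genes of the same level, at percentile 35.6 of the matched random lists, whose median was -0.32.

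In the list of maternal mRNA decay and storage 6 of 57 measured members were higher and 15 lower in cKO (5 and 14 adjusted over the list alone), and 36 did not pass. The list median was -0.21 (camera adjusted p = 0.0286, and adjusted p = 0.459 with an estimated correlation). Parn, a poly(A)-specific ribonuclease, rose from 472 ± 114 to 3142 ± 673 (log2 fold change 2.75 ± 0.18, adjusted p = 4.49e-08). Tent5c, a poly(A) polymerase, fell from 9917 ± 1484 to 3851 ± 620.4. In the list of meiotic maturation 5 of 51 measured members were higher and 17 lower in cKO (5 and 17 adjusted over the list alone), and 29 did not pass. The median log2 fold change was -0.16 (camera adjusted p = 0.0195, and adjusted p = 0.459 with an estimated correlation). The spindle checkpoint kinase Bub1b fell from 7659 ± 1737 to 3203 ± 667 and cyclin B1 (Ccnb1) from 16521 ± 2434 to 10064 ± 1218, the latter not under quantile normalization (adjusted p = 0.861). In the list of RNA polymerase II transcription 9 of 85 measured members were higher and 20 lower in cKO (8 and 19 adjusted over the list alone), and 56 did not pass. Its median was -0.13 (camera adjusted p = 0.0427, and adjusted p = 0.236 with an estimated correlation). Taf8, a subunit of TFIID, fell from 1279.9 ± 62.0 to 559 ± 113, whereas Cdk9, the kinase of the elongation factor P-TEFb, rose from 71.9 ± 16.8 to 211 ± 33.3. The medians of these 3 lists were above 0 under a common total per oocyte (0.05, 0.10 and 0.13), where 11, 13 and 17 members were higher and 9, 6 and 5 lower, and lay at percentiles 21.5, 76.7 and 36.4 of the matched random lists. All tested genes had a median of 0.30 under a common total, with 5530 higher and 1559 lower. Under quantile normalization meiotic maturation had 10 members higher and 9 lower. None of the 3 lists passed with a mean of at least 50, under a common total (adjusted p = 0.0669, 0.161 and 0.244) or under quantile normalization (adjusted p = 0.750, 0.841 and 0.750). Without control unit 6323 meiotic maturation and RNA polymerase II transcription no longer passed (adjusted p = 0.0555 and 0.0593), and the latter also without control unit 6295 or cKO unit 6302 (adjusted p = 0.0507 and 0.0724).

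Lists of stress responses were compared next. In the heat shock list 0 of 22 measured members were higher and 11 lower in cKO (0 and 11 adjusted over the list alone), and 11 did not pass. The median was -0.49 (camera adjusted p = 0.00121, and adjusted p = 0.426 with an estimated correlation). It lay at percentile 1.00 of the matched random lists, and the list no longer passed under quantile normalization (adjusted p = 0.394). Members lower numbered 7 under a common total and 8 under quantile normalization, with 0 and 1 higher. The chaperone genes Hsp90aa1 and Hspa4l fell from 23002 ± 5816 to 7837 ± 1909 (log2 fold change -1.60 ± 0.19) and from 582 ± 193 to 264 ± 60.3. In the list of the unfolded protein and integrated stress response 6 of 37 measured members were higher and 14 lower in cKO (6 and 14 adjusted over the list alone), and 17 did not pass. The list median was -0.32 (camera adjusted p = 0.0359, and adjusted p = 0.459 with an estimated correlation). The endoplasmic reticulum gene Sdf2l1 fell from 331 ± 31.5 to 102 ± 10.6. In contrast, Phgdh, the first enzyme of serine synthesis, rose from 359 ± 33.7 to 979 ± 132. Trib3 rose from 6.88 ± 2.62 to 29.04 ± 3.42. The list no longer passed without control unit 6323 or cKO unit 6300 (adjusted p = 0.0593 and 0.0521), under a common total (8 higher and 8 lower, median -0.06, adjusted p = 0.0639), under quantile normalization (3 higher and 12 lower, adjusted p = 0.394) or with a mean of at least 50 (adjusted p = 0.117). The p53 response list did not pass, with 10 higher and 6 lower of 29 measured (10 and 6 adjusted over the list alone; camera adjusted p = 0.651). Within it Ccng1 rose from 38.9 ± 5.34 to 390.4 ± 132 (log2 fold change 3.19 ± 0.21). Pmaip1, a pro-apoptotic BH3-only protein, rose from 2.40 ± 3.42 to 98.2 ± 60.6 and the cell cycle inhibitor Cdkn1a from 9.86 ± 2.33 to 46.2 ± 14.5. Without control unit 6295 the control mean of Pmaip1 was 0.9345. Mdm4, an inhibitor of p53, fell from 24193 ± 3742 to 7426 ± 1801 (log2 fold change -1.74 ± 0.16). The apoptosis and autophagy list did not pass either (9 higher and 7 lower of 36 measured (9 and 7 adjusted over the list alone; camera adjusted p = 0.651)). Bcl2l10, an anti-apoptotic oocyte protein, fell from 28686 ± 6117 to 12583 ± 951 and the autophagy receptor Sqstm1 rose from 230.1 ± 90.9 to 853 ± 246.

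Genes of energy metabolism were compared by genome. In the list of nuclear oxidative phosphorylation 5 of 84 measured members were higher and 10 lower in cKO (4 and 5 adjusted over the list alone), and 69 did not pass. The median was -0.22 (camera adjusted p = 0.00819, and adjusted p = 0.735 with an estimated correlation). It became 0.04 under a common total per oocyte, with 8 members higher and 4 lower, and lay at percentile 28.7 of the matched random lists. The median of all tested genes under a common total was 0.30. Ndufs4, a complex I subunit, fell from 1076 ± 284 to 375 ± 72.5 and Uqcrc1, a complex III subunit, rose from 99.98 ± 28.2 to 374 ± 138. In the mitochondrially encoded list 6 of 14 measured members were higher and 0 lower in cKO (6 and 0 adjusted over the list alone), and 8 did not pass. Its median was 0.65 (camera adjusted p = 0.0427, and adjusted p = 0.735 with an estimated correlation). The members named by the rule were mostly transfer RNA genes of low count, such as mt-Tp, which rose from 8.85 ± 4.40 to 33.7 ± 10.3. The complex I gene mt-Nd6, which overlaps mt-Nd5, rose from 213 ± 91.7 to 396 ± 114. The list no longer passed without any 1 of control units 6296 and 6323 and cKO units 6299, 6300, 6301 and 6302 (adjusted p from 0.0614 to 0.134). It was also lost under a common total (adjusted p = 0.0765), with log2 of the unit mean (0.0676), with fry (0.0569) and with either other filter (0.157 and 0.179). Nuclear oxidative phosphorylation no longer passed without control unit 6296 (adjusted p = 0.0864), under a common total (0.0765), under quantile normalization (0.841), with a mean of at least 50 (0.104) or with fry (0.351). The glycolysis list did not pass (3 higher and 5 lower of 18 measured (3 and 5 adjusted over the list alone; camera adjusted p = 0.365)). Ldhb, lactate dehydrogenase B, fell from 81532 ± 9773 to 38203 ± 2878 and Gapdh rose from 884 ± 203 to 1991 ± 270.4.

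The list of the SUMO pathway itself did not pass, with 4 higher and 3 lower of 24 measured (3 and 3 adjusted over the list alone; camera adjusted p = 0.612). Under a common total per oocyte 8 members were higher and 1 lower, against 5530 and 1559 of all tested genes. The SUMO ligase genes Nsmce2 and Pias1 fell from 4115 ± 836 to 2489 ± 304 and from 4076 ± 305 to 2876 ± 214. The SUMO protease gene Senp5 rose from 282 ± 29.5 to 377 ± 25.2. The call of Pias1 was lost under both other scalings (adjusted p = 0.0665 and 0.0966), and that of Senp5 without control unit 6292 (adjusted p = 0.0501). The chromatin repressor list did not pass, with 12 higher and 9 lower of 67 measured (12 and 7 adjusted over the list alone; camera adjusted p = 0.548). The maintenance DNA methyltransferase Dnmt1 fell from 16796 ± 3429.6 to 7444 ± 2529 (log2 fold change -1.26 ± 0.19). The Polycomb genes Cbx7 and Ring1 rose from 21.4 ± 4.06 to 98.3 ± 16.3 and from 2.91 ± 1.52 to 13.6 ± 2.71. Setdb1, a histone H3 lysine methyltransferase, rose from 912 ± 143 to 1269 ± 156 and Trim28, its partner, from 391 ± 119 to 604 ± 177 (adjusted p = 0.0109 and 0.0289). The call of Trim28 was lost without any 1 of control units 6292, 6295 and 6296 and cKO units 6301 and 6322 (adjusted p from 0.0647 to 0.0730). With all units it was lost with edgeR and DESeq2 on reads summed per unit (adjusted p = 0.0755 and 0.0675). Kdm1b, a histone demethylase, was counted at 1331 ± 229.9 in control and 1687 ± 535 in cKO (adjusted p = 0.315, but 0.0406 without cKO unit 6301, 0.0400 with DESeq2 on single oocytes and 0.0487 with a block of the oocyte numbers). The germline and piRNA list did not pass, with 10 higher and 13 lower of 35 measured (10 and 13 adjusted over the list alone; camera adjusted p = 0.103). Gtsf1, a piRNA pathway factor, fell from 7349.7 ± 1888 to 1767 ± 313 (log2 fold change -2.03 ± 0.17). Dppa4 fell from 241 ± 45.5 to 66.2 ± 19.7 and Tex19.2 rose from 34.4 ± 11.4 to 368 ± 111 (log2 fold change 3.46 ± 0.36). The meiotic prophase list had 8 higher and 9 lower of 35 measured (8 and 10 adjusted over the list alone; camera adjusted p = 0.623). Tex12, of the synaptonemal complex, fell from 547 ± 186 to 72.3 ± 8.05 and Trip13 rose from 62.4 ± 6.87 to 259 ± 60.1.

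Markers of the other cells that can accompany an oocyte were compared as well. The granulosa and cumulus list had 4 higher and 1 lower of 15 measured (4 and 1 adjusted over the list alone; camera adjusted p = 0.488). The receptor gene Fshr rose from 6.80 ± 5.43 to 165 ± 53.8 (log2 fold change 4.88 ± 0.42), with a control mean of 4.49 without control unit 6295. Inha was counted at 28.8 ± 32.6 in control and 53.4 ± 29.7 in cKO (adjusted p = 0.390) and Amh at 0.191 ± 0.316 in control and 0.543 ± 0.618 in cKO. The theca and stroma list did not pass, with 4 higher and 0 lower of 5 measured (4 and 1 adjusted over the list alone; camera adjusted p = 0.308). In it Dcn, a matrix proteoglycan, rose from 17.9 ± 10.2 to 132 ± 74.5. Star rose to 20.8 (13.3 without cKO unit 6301), Aldh1a1 to 29.2 and Hsd3b1 to 18.3. These 3 calls were lost under quantile normalization and, for Star and Aldh1a1, with log2 of the unit mean. Those of Star and Aldh1a1 were also lost without any 1 of control units 6295 and 6297 and cKO units 6301 and 6302, of Star without unit 6296 and of Aldh1a1 without unit 6292 (adjusted p from 0.0521 to 0.0849). Both were lost without units 6322 and 6323 together (adjusted p = 0.0512 and 0.0502), and Star with the unit as a random block (0.0729). In the immune and blood list 4 of 5 measured members were higher and 0 lower in cKO (4 and 0 adjusted over the list alone), and 1 did not pass. The list median was 1.40 (camera adjusted p = 0.0359, and adjusted p = 0.236 with an estimated correlation). Adgre1, a macrophage marker, had 2 reads over the control oocytes and 1328 over the cKO oocytes, a ratio of 829 with a 95% counting interval of 229 to 6852. H2-Aa rose from 60.2 ± 18.4 to 159 ± 20.2. Cd74 and Lyz2, which macrophages express strongly, were at 0.425 ± 0.718 and 1.19 ± 1.03 in cKO. The list no longer passed without control unit 6323 or cKO unit 6302 (adjusted p = 0.0536 and 0.0504) or without units 6322 and 6323 together (0.0531). It was also lost under a common total (adjusted p = 0.0669), under quantile normalization (2 higher, median 0.77, adjusted p = 0.102), with the oocyte of the unmatched column as its own unit (0.0617) and with a filter of at least 1 in at least 2 oocytes (0.0809). The endothelial list had 1 higher and 3 lower of 6 measured (1 and 3 adjusted over the list alone; camera adjusted p = 0.0802). Flt1 fell from 53.2 ± 8.05 to 6.46 ± 1.82 and Pecam1 from 407 ± 130.4 to 101 ± 30.9. Over all marker genes with a record in the table, including those too low to be tested, 4 of 28 granulosa, 4 of 12 theca, 4 of 12 immune and 1 of 9 endothelial genes were higher in cKO.

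The remaining lists did not pass the set test. DNA repair had 4 higher and 10 lower of 64 measured (3 and 9 adjusted over the list alone; camera adjusted p = 0.0790). Splicing factors had 7 higher and 14 lower of 65 measured (7 and 12 adjusted over the list alone; camera adjusted p = 0.0790). Cytosolic ribosomal proteins had 6 higher and 7 lower of 86 measured (4 and 3 adjusted over the list alone; camera adjusted p = 0.0579). The ribosomal list passed without any 1 of control units 6295, 6297 and 6323 and cKO unit 6301 (adjusted p from 0.00172 to 0.0435). The splicing list passed without control unit 6292 (adjusted p = 0.0471). Under a common total per oocyte the balance of these 3 lists turned, to 16 higher and 5 lower for DNA repair, 15 and 3 for splicing factors and 13 and 2 for ribosomal proteins (medians 0.14, 0.18 and 0.08). All tested genes shifted the same way there, with 5530 higher, 1559 lower and a median of 0.30. With a filter of at least 1 in at least 2 oocytes these lists passed (adjusted p = 0.00396, 0.00406 and 0.00224), as did the germline and endothelial lists (0.0294 and 0.0356). Cholesterol synthesis had 7 higher and 3 lower of 22 measured (7 and 3 adjusted over the list alone; camera adjusted p = 0.651). Its member Tm7sf2 rose from 29.5 ± 6.27 to 192 ± 33.8. The cytoskeleton list had 5 higher and 5 lower of 28 measured (5 and 5 adjusted over the list alone; camera adjusted p = 0.651). Rdx, a linker of actin to the membrane, fell from 27478 ± 2335 to 10522 ± 1953, and the tubulin gene Tubb2a rose from 8039 ± 1538 to 13399 ± 927. Imprinted genes had 6 higher and 5 lower of 31 measured (6 and 5 adjusted over the list alone; camera adjusted p = 0.874). The interferon response had 8 higher and 2 lower of 21 measured (10 and 2 adjusted over the list alone; camera adjusted p = 0.631). Replication-dependent histones had 2 higher and 2 lower of 22 measured (2 and 1 adjusted over the list alone; camera adjusted p = 0.714). Spermatid genes had 2 higher and 3 lower of 11 measured (2 and 3 adjusted over the list alone; camera adjusted p = 0.537). The median log2 fold change and the direction of the set test differed in sign for the SUMO, apoptosis, cytoskeleton, imprinted, meiotic prophase and histone lists, and the mean and the test for chromatin repressors. The balance of calls also turned with scaling for other lists. Under a common total this held for the germline (11 higher, 10 lower) and meiotic prophase (15 and 8) lists. Under quantile normalization it held for the apoptosis (4 and 6) and imprinted (6 and 7) lists, while histones had 0 and 6 and ribosomal proteins 7 and 6. Under a common total the apoptosis, imprinted, cytoskeleton and histone lists had 12 and 2, 9 and 1, 9 and 4, and 4 and 1. All tested genes had 2968 and 3927 under quantile normalization. In all, 11 of 30 lists passed camera with its preset correlation, and none passed with an estimated correlation (4 at an unadjusted p below 0.05), while fry passed 18, among them the germline, imprinted, interferon, p53, DNA repair, cholesterol, granulosa, theca and endothelial lists. Of 100 splits of the units into 5 and 5, the real one included, 14 gave at least 11 lists.

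To ask whether more genes were represented in cKO oocytes, every oocyte was thinned to 4902488 reads. A gene was counted as detected with at least 5 reads. Control units had 13216 ± 143 detected genes and cKO units 15413 ± 692, a difference of 2197 (exact two-sided permutation test, p = 0.00794, the smallest possible). Single oocytes ranged from 12796 to 13485 in control and from 14594 to 17132 in cKO. The 500 most abundant genes held 44.0% to 49.6% of the reads of control oocytes and 34.1% to 40.04% of those of cKO oocytes.

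The cKO oocytes were also less alike. The distance of an oocyte to the mean profile of the other units of its group, 1 minus the Spearman correlation over the tested genes, was 0.0231 ± 0.0050 in control and 0.0439 ± 0.0091 in cKO. The difference of 0.0209 had p = 0.00794 in the exact permutation test over 5 units per group.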

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

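Tests of granulosa RNA, of depth, of reads shared between copies, of a single extreme unit and of the scaling of the libraries, and both counts of splits, were chosen after the results were seen, and the reading of the scaling, shared-read and granulosa tests was tightened after their values were seen. The tests without the 500 most abundant genes and of the abundance of the oocyte factors were written before their results.

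Within groups of 5 units, 374 sets of unit values were examined for a unit far from the other 4, and 31 were found, where chance gives about 1 in 20, or 18.7. Control unit 6296 accounted for 11 of them, cKO unit 6301 for 6, control unit 6323 for 5, and units 6295, 6297, 6299, 6300 and 6322 for 1 to 3 each. The gap to the nearest unit, as a share of the range (above 0.71 in each case), is given for each.

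Unit 6296 lay highest in control for Ube2i (0.882), Mnat1 (0.762), Tdrd12 (0.726), Npm2 (0.897), Birc5 (0.759), Ndufb5 (0.740) and the meiotic prophase list score (0.903), and lowest for Cdh2 (0.749), H2-Aa (0.824) and Sgce (0.902). Ube2i remained lower in cKO without this unit, with a log2 fold change of -0.98. Control unit 6323 held all control reads of Igha, Ighe, Itpkb and Zscan4a, and unit 6296 those of Adgre1, so the gap was 1 for each of these genes. Unit 6323 lay lowest for Igf1os (0.740). Control unit 6295 lay highest for Camk2g (0.741) and Trib3 (0.740) and lowest for the granulosa list score (0.724), and control unit 6297 lay lowest for Tex19.2 (0.718).

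Among cKO units, 6301 lay highest for Usp17lb (0.714), Bpifc (0.718), Rpl10l (0.871), Pramef25 (0.820), the histone list score (0.787) and the distance of oocytes to their group (0.843). Without unit 6301 that distance still differed by 0.0178 between the groups. Unit 6300 lay highest for Hormad2 (0.741) and unit 6299 for Mcl1 (0.752). Unit 6322 lay lowest for mt-Tc (0.864), mt-Tn (0.773) and the nuclear oxidative phosphorylation list score (0.765).

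Chance could be excluded for the count of changed genes, since only 1 of 100 splits of the 10 units into 5 and 5, the real one, gave as many as 7059, and the highest other gave 0. It was not excluded for the count of gene lists: 14 of the 100 splits gave at least the 11 of the real one, and the highest other gave 18.

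More genes were detected in cKO oocytes than in control oocytes. Depth is argued against, because cKO oocytes had fewer reads and yet 1311 more genes with at least 5 reads before thinning (exact p = 0.0317). A few abundant genes taking fewer reads are argued against by a difference of 1872 without the 500 most abundant genes. RNA of granulosa cells stays open: 4 of 28 markers with a record were higher and 1 lower, with 15 of the 28 tested. The untested ones did not reach a value of 10 in 8 oocytes. Among them Amh, Foxl2 and Amhr2 were near the floor in cKO, at 0.543 ± 0.618, 1.26 ± 0.441 and 0.996 ± 1.11. For theca and immune markers 4 of 12 each with a record were higher, which leaves RNA of those cells open, although Cd74 and Lyz2 stayed near the floor. List members without a record, such as Col1a1, Col3a1 and Tyrobp, are not in these counts. A broader transcript set in cKO oocytes is therefore only a hypothesis beside these.

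The rise of the two-cell list was not the work of 1 extreme unit, since its median log2 fold change stayed at 2.84 or more in each of 10 fits without 1 unit. Whether it reflects many genes or reads of few active copies spread over near-identical ones of the same family cannot be told apart here. The 6 members of no multi-copy family had a median of 0.23, with 1 higher (Zfp54, 3.64 ± 1.69 in control and 61.6 ± 66.3 in cKO) and 1 lower (Usp26, 52.1 ± 12.5 in control and 22.1 ± 9.89 in cKO). That median does not decide the question, because members such as Arg2 (4806 ± 555) and Nr5a2 (213 ± 43.7) were already well counted in control. Tmem92 was uneven in cKO (19.3 ± 3.32 in control and 519 ± 857 in cKO) and did not pass. A release of these families in cKO stays open as the biological explanation.

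Under the deposited scaling the fall of the oocyte factors was larger than that of most random lists matched on mean level, with the list median at percentile 0.44. This was 1 of 30 lists compared so, and the random lists ignore correlation between genes. Other lists also lay near an end, such as the cytoskeleton (99.91), mitochondrially encoded (99.88) and unfolded protein (0.98) lists. Whether the scaling of the libraries produced the fall was not decided. The list median was -0.35 under a common total per oocyte, past the threshold. It was -0.10 under quantile normalization, not past it (adjusted p = 0.750). Quantile normalization gives every oocyte the same distribution of values, so it shrinks or removes a fall shared by the most abundant genes. The 500 most abundant genes held 34.1% to 40.04% of the reads of cKO oocytes and 44.0% to 49.6% of those of control oocytes. The result under quantile normalization therefore does not count for or against a fall. The calls under both scalings used camera's preset correlation, and with an estimated one the list did not pass as deposited (adjusted p = 0.110). Without spike-in values the amount of RNA per oocyte stays open, and a lower level in cKO is untested as the biological explanation.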

How the results depend on the processing

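The filter to genes that overlap no other gene, the detection counts without thinning or without the 500 most abundant genes, the spread after thinning, and both exact tests of list scores were added after the data were seen. Across the 29 other settings of the gene-level fit, of which 28 were planned, the lower level of Ube2i kept its direction and its call (log2 fold change from -1.09 to -0.76). The counts of changed genes stayed within 1.5 times of 7059 except where fewer genes could pass: 4315 (2067 higher) with a mean of at least 50, 4081 (986 lower) with an absolute log2 fold change of at least 1, and 3591 (2262 higher, 1329 lower) among genes that overlap no other. Genes higher numbered 6269 with a filter of at least 1 in at least 2 oocytes, which tested 26131 genes against 15326. The genes it added did not reach 10 in 8 oocytes. Among the 15326, 41.3% of the lowest of 5 level bins were higher. Genes lower numbered 1559 with a common total per oocyte. That scaling raises cKO values against control, because the mean normalised total was 7623827 in cKO and 9198666 in control. Without 1 unit the count ranged from 6177 to 7140. Depth limits the low genes, whose ratios carry wide counting intervals.

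The number of gene lists past the threshold, 11, was less stable. It was 14 with a filter of at least 1 in at least 2 oocytes, 4 with a mean of at least 50, 4 with a common total per oocyte, 2 with quantile normalization, 0 with an estimated correlation (4 at an unadjusted p below 0.05) and 18 with fry, and it ranged from 7 (without control unit 6323) to 12 without 1 unit. An exact permutation test of mean list scores, tried first, gave 21 lists. It was then replaced by a test of median scores, because the mean over all genes is pulled up by the strongest rises, and that gave 14. Under quantile normalization Dppa3 (0.20), Nlrp5 (0.10) and the set test of meiotic maturation (median -0.00938) turned direction, and the cause was not tested.

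Of 154 named genes 106 kept direction and call in every alternative that tested them (117 of the 154 with a mean of at least 50 and 89 among genes that overlap no other), with 98 results weaker, 6 stronger and 2 reversed against 4258 the same. Of 30 lists 8 did (26 with a mean of at least 50), with 55 weaker, 22 stronger, 1 reversed and 638 the same. The differences in detected genes (1311 to 2636) and in spread (0.0178 to 0.0261) kept direction and p below the threshold in all alternatives.

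The oocyte numbers shared between groups were not taken as pairs in the main fit. Of 16 pairs 6 had a correlation over 0.1 (-0.154 to 0.309), and 4 of 16 control oocytes correlated best with their own number. These values do not exclude some pairing. With the number as a replicate block 9449 genes passed, against 9339 with each oocyte as a replicate and no block.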

Other observations

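The groups described here were picked after 220 families of gene symbols, the gene types and 20 chromosomes had been looked through, so they are hypotheses. The tests of matched level and of plasma cell markers were written before their results, but the reading of the plasma cell test was tightened afterwards, which left open a source it had first argued against. The test of neighbours was revised after a first result.

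Genes of sensory receptors, keratins and unprocessed pseudogenes were higher in cKO as classes. Of 92 olfactory receptor genes (Olfr) 67 were higher (Fisher's exact test, adjusted p = 4.40e-17 over the 220 families), of 44 vomeronasal receptor genes (Vmn) 37, of 23 keratin genes 17, of 16 Obox genes 12 and of 19 Zscan genes 13. In contrast, 17 of 24 Fbxw genes, which encode F-box proteins, and 9 of 13 Nlrp genes were lower. Of 149 unprocessed pseudogenes 104 were higher, against 3118 of 12599 protein-coding genes. These directions held under a common total and under quantile normalization. Members of such families share reads, so single genes are uncertain. Long intergenic RNA genes and processed pseudogenes also had positive medians (0.31 and 0.61), which turned to -0.16 and -0.06 under quantile normalization. The median of all tested genes was -0.11 there.

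At the immunoglobulin heavy chain locus on chromosome 12, Ighm rose from 626 ± 118 to 1577 ± 228 and Ighg1 from 811 ± 428 to 2964 ± 278, besides Igha and Ighe. Ighg2c rose from 3.02 ± 2.22 to 64.3 ± 40.7 and 5 of 6 tested variable segments rose, while Ighg2b, at 1116 ± 774 in control and 1551 ± 796 in cKO, and Ighg3, at 225 ± 160.0 in control and 363 ± 257 in cKO, did not pass (adjusted p = 0.451 and 0.541). RNA of B or plasma cells stays open as the source. The variable segments would go with it, whereas 1 of 10 markers with a record was higher (Iglc2) and Jchain was at 1.02 ± 1.56 in cKO. Ms4a1 fell from 1448 ± 99.9 to 689 ± 108, Tnfrsf17 from 12.9 ± 6.44 to 2.00 ± 0.977 and Derl3 from 1296 ± 65.8 to 990 ± 130. Sdc1 and Prdm1 did not pass. Only 6 of the markers were tested, and all but 1 of these had a mean of at least 50 in control, which could hide a small share.

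One hypothesis was that the rise of these classes comes from their low level, since low genes rose more often. The class medians lay at percentile 100 of 10000 random lists matched on mean level for unprocessed pseudogenes, olfactory and vomeronasal receptor genes, and keratin genes. They were 2.02, 2.07 and 2.09, against 0.33, 0.44 and 0.12 for the random lists. The Fbxw median, -0.93, lay at percentile 0. These classes were picked by their calls in the same data, which made extreme medians likely, and the mean level included the cKO oocytes. The percentiles therefore describe the classes and do not decide the hypothesis. On the X chromosome 34.8% of 528 genes were higher against 26.9% on autosomes, and the median of 0.24 lay at percentile 99.96 of matched lists. Under quantile normalization the X median was 0.01 (144 higher, 123 lower), where that of all tested genes was -0.11 (2968 higher, 3927 lower). A second hypothesis was that higher genes lie side by side. Of 10461 neighbouring pairs of different families, both genes were higher in 600, against a mean of 591 in 1000 label permutations (p = 0.334). A first form, which drew labels over all tested genes, gave a mean of 669 and p = 1, so neither form found clustering.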
